A study of Mus musculus with 4 samples.

How the data were processed

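The samples were 4 arrays of sorted naive CD4 T cells, 2 labelled wild type and 2 labelled knockout. Per the labels' protocols, total RNA was extracted with Trizol and 5 micrograms were made into biotinylated cRNA. The deposited values are intensities, MAS5 signals on a linear scale with 1 value per probe set; MAS5 is named in the submitters' processing notes, and its version and settings are not given in the sources used here. The values themselves show that each array had been scaled to the same trimmed mean, 500.003 when 2% of values are trimmed at each end. The table has no detection calls, so signal over background is not known per probe set. The small number of arrays limits the precision that can be stated, and so does the difference between arrays numbered 1 and 2 described below.

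The table held 45101 probe sets, of which 64 controls were left out of all tests. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 had none, and only the first kind was named. Of these, 34741 symbols were updated through their Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names and for which genes neighbour each other; no coordinates are given because no build is named for the array values. Signals were transformed as log2(signal + 15.3), where 15.3 is the 25% quantile of all values. The 22518 probe sets whose mean over all arrays exceeded the median of such means were kept, which left 10211 genes. Each gene was represented by its kept probe set with the highest mean.

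Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. The reported fit has no block. Probe sets at least 2-fold apart in every comparison of a knockout-labelled with a wild-type array were counted without a test, and the count was set beside those of the other groupings. Before the data were examined, 23 gene lists were fixed; 20 had at least 5 kept members and were tested with camera (two-sided, preset correlation 0.01, Benjamini-Hochberg over the 20). Counts adjusted over the list alone use limma p-values adjusted within a list. Genes were named by a rule fixed beforehand. It takes Furin, the genes past the threshold or else up to 8 per direction that were at least 2-fold apart in all comparisons, up to 3 genes of the largest change per list, and for lists of other cell types also the 2 brightest. Genes named outside this rule, chosen after their values were seen, are Junb, Ppp1r15a, Nr4a2, Ier2, Cd69, Egr1, Egr2, Egr3, Nr4a1, Nr4a3, Myc, Cd44, Ahnak, Ms4a1, Cd79a and Cd22, and those of the families in the closing section.

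The labels number the arrays 1 and 2 in each group but state no shared animal, batch or day. The hybridisation controls, which do not depend on the cells, show that the numbers follow a technical difference, so the array number was treated as a batch. Deviations of same-numbered arrays from their group means correlated at 0.80 across probe sets, which are not independent replicates, and 7791 probe sets differed between the numbers in the limma fit with both terms. The blocked fit has 1 residual degree of freedom and the reported fit 2. The median residual SD was 0.149 with the block and 0.408 without it.

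The tests were checked on simulated data with the real means and the real difference between pairs, with 200 of 22518 probe sets changed in each of 20 simulations of the knockout against wild-type comparison. The outcome depended on how residual variances were drawn. In the version written first, which took the blocked residual SDs, each with 1 degree of freedom, as true SDs, 0% of 2-fold, 4-fold and 16-fold changes were recovered without the block, with it, or with the block and a trended prior. A second version was added because of that outcome. It draws variances from the trended prior that limma estimated with the block, and so favours that fit. Without the block, 0% were again recovered at all 3 sizes. With the block 2.99% of 2-fold, 88.1% of 4-fold and 99.7% of 16-fold changes were recovered, and 1.67% of calls were false. With the block and a trended prior 67.6%, 98.5% and 100% were recovered, but 12.3% of calls were false, above the 5% aimed at. A fit without the block that calls 0 probe sets is therefore not evidence that none differed. Camera called 50 of 50 lists of 30 probe sets shifted by 0.5, and 2 or 7 of 1000 unshifted lists under the first or second version; these simulated lists had no correlation between genes, so this says nothing of lists whose genes vary together.

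Alternatives fixed before the data were examined covered the pseudocount, the filter, quantile normalization and median centring, a trended or robust prior, the array number as a block, each array left out, an adjusted p under 0.10, a 1.5-fold limit, an estimated correlation, fry, and the mean of a gene's probe sets. Combinations of the block with other choices, and the count of probe sets 2-fold apart within both same-numbered pairs, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.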

Results

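Gene expression was measured in naive helper T cells, sorted as CD4 and CD62L positive and CD44 negative, from mice of 10 to 11 weeks. Furin is a proprotein convertase, a protease that cuts precursor proteins into their mature forms, and the mice labelled knockout carried a floxed furin gene with a Cre recombinase driven by the CD4 promoter, which acts in T cells. The littermates labelled wild type carried the floxed gene without Cre. Each group had 2 Affymetrix mouse whole-genome arrays, 4 in all, and this number limits the precision of every value. The labels do not say that the arrays of a group came from separate animals, so the p-values measure only the spread between these samples. Values are MAS5 signals on the log2(signal + 15.3) scale, which understates the change of dim probe sets, and differences are knockout minus wild type.

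The arrays fell into pairs by their number rather than by genotype. The geometric mean of the bacterial controls BioB, BioC, BioDn and CreX, which are added before hybridisation and do not come from the cells, was 5.56-fold brighter on wild-type array 2 than on wild-type array 1 and 5.45-fold brighter on knockout array 2 than on knockout array 1. Dap, a bacterial control outside this mean, had signals of 299.7 and 377 on the wild-type and knockout arrays numbered 1. On those numbered 2 it was at 7.2 and 3.2, below the added 15.3, so it was close to absent there and is not set against the other controls. The ratio of the 3' to the 5' Gapdh control was 4.09 and 3.35 on the wild-type and knockout arrays numbered 1, and 0.905 and 0.934 on those numbered 2, while that of actin was 1.23 and 1.20 on arrays numbered 1 and 1.72 and 1.77 on those numbered 2. The first principal component, with 78.7% of the variance, separated the numbers. Differences within the arrays numbered 1 (pair 1) and those numbered 2 (pair 2) therefore stand after the SE of most genes named below, in this order, and the SE is that of the fit without a block unless stated. A block for the pair leaves each difference as it is and changes its SE.

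**Figure D1:**
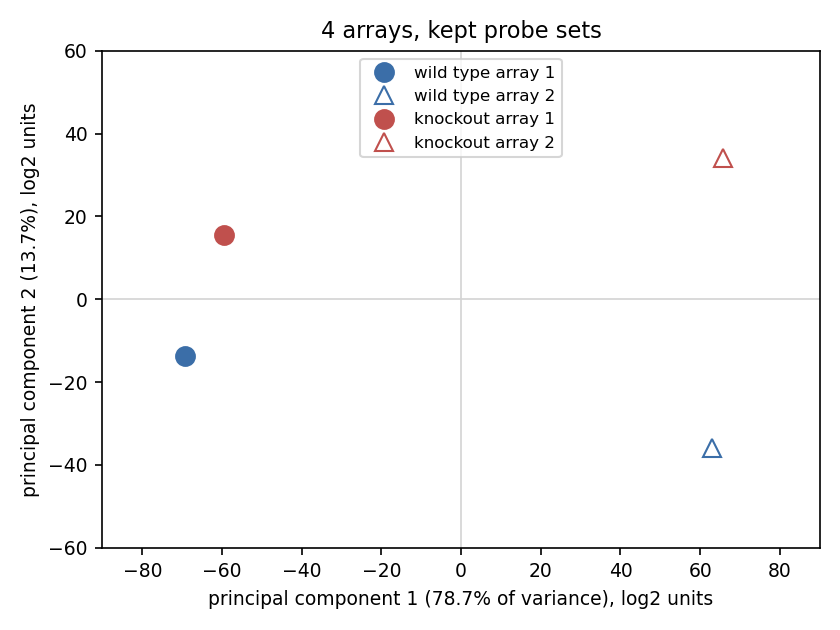
Scores of the 4 arrays on the first 2 principal components of the kept probe sets, in log2 units; colour gives the genotype label and the symbol the array number. Component 1 (78.7% of the variance) separates arrays numbered 1 from arrays numbered 2, and component 2 (13.7%) separates the genotype labels.

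The targeted gene was examined first. The only Furin probe set had a mean signal of 389.5 ± 64.5 (SD, n = 2) in the wild-type arrays and 419 ± 39.2 (SD, n = 2) in the arrays labelled knockout. The difference was 0.11 on the log2 scale (SE 0.34, 95% interval -0.77 to 0.99). Within pairs it was -0.15 and 0.36, and with the pair as a block its interval ran from -0.43 to 0.65. The labels do not say which part of the gene was deleted, and the probe set may lie outside it, so this value checks neither the deletion nor the labels; directions below are those of the arrays labelled knockout. The 7 measured neighbours of Furin in the fixed list showed no common shift, with a median of -0.11 and within-pair medians of -0.05 and 0.04, and the largest difference among them was 0.32 for Unc45a (SE 0.35, pairs 0.25 and 0.39), which turned to -0.06 with the mean of its probe sets.

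Across the genome, the clearest differences with the pair as a block were higher levels in the knockout-labelled arrays of Jun and Fos, subunits of the transcription factor AP-1, of Tgm2, a transglutaminase, of Hspa1a, an inducible heat shock protein of the HSP70 family, and of Dtl, an adaptor of a ubiquitin ligase. Jun was higher by 4.63 (SE 0.19 with the block, 0.32 without), Fos by 4.02 (SE 0.24 and 0.52), Tgm2 by 3.90 (SE 0.26 and 0.38), Hspa1a by 3.44 (SE 0.19 and 1.12) and Dtl by 2.90 (SE 0.20 and 0.49). In pair 1 these differences were 4.74, 3.67, 4.34, 3.54 and 2.76, and in pair 2 they were 4.51, 4.37, 3.46, 3.34 and 3.04. In the limma fit without a block, 0 of 22518 kept probe sets passed a Benjamini-Hochberg adjusted p of 0.05. The smallest adjusted p was 0.888, and 145 probe sets had an unadjusted p under 0.05, where chance gives 1126. With the pair as a block, limma called 6 probe sets, all of which rose, with 1897 at an unadjusted p under 0.05. They were 2 of Jun and 1 each of Fos, Hspa1a, Dtl and Tgm2. The 5 kept probe sets of Tgm2 ran from 0.72 to 3.90, the value given above, and 4 of them were at least 2-fold apart in all comparisons. Hspa1a has a near-identical copy, Hspa1b, so the signals of this pair of genes are uncertain, and with 1 array left out the Hspa1a difference ranged from 2.21 to 4.67. This blocked count ranged from 0 to 260 under further settings, with 260 for a trended prior; the block named below is the fit without one unless stated.

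In 37 probe sets both knockout-labelled arrays lay at least 2-fold above both wild-type arrays, and in 9 both lay at least 2-fold below. The other groupings of the arrays gave 2500 such probe sets for array number and 5 for the crossed grouping. None of the following 7 genes passed limma at 0.05 over all probe sets in the fits with and without the block, and all passed with the block and a trended prior. Gm4951, a member of the interferon-inducible GTPases, was higher by 3.84 (SE 0.51, pairs 3.04 and 4.64), H3f3b, which encodes a variant histone, by 3.61 (SE 0.53, pairs 4.33 and 2.88), Iigp1, another interferon-inducible GTPase, by 2.28 (SE 0.37, pairs 1.85 and 2.70), and Dusp1, a MAP kinase phosphatase, by 2.27 (SE 0.64, pairs 2.76 and 1.78). Without knockout replicate 1 Dusp1 was at 1.47. Among lower genes, Ncmap differed by -3.12 (SE 0.47, pairs -2.46 and -3.77), Slc16a4, a solute carrier, by -2.05 (SE 0.39, pairs -2.02 and -2.07) and Tspan9, a tetraspanin, by -1.78 (SE 0.32, pairs -1.62 and -1.93). For Rhbdd3, Rpf1 and Zmym3 the probe set that lay 2-fold lower was not the brightest of its gene, which differed by 0.12, -0.003 and -0.24. With the pseudocount at the median Ncmap was at -2.04.

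**Figure D2:**
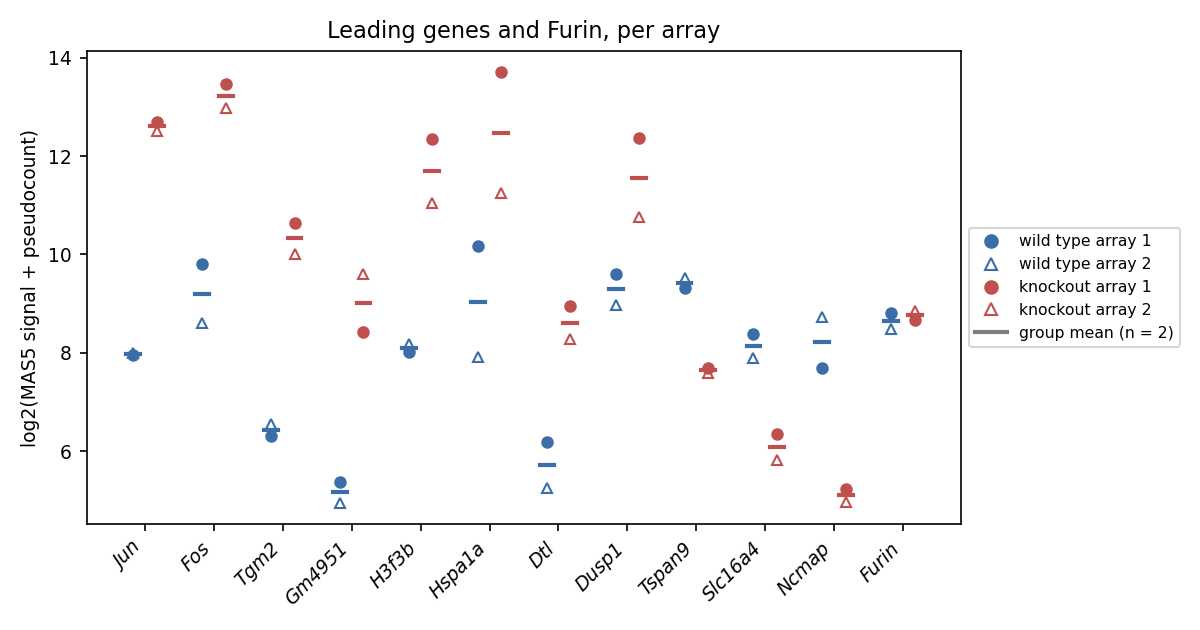
Log2(MAS5 signal + 15.3) of leading genes and Furin on each of the 4 arrays; colour gives the genotype label, the symbol the array number, and the bar the mean of 2 arrays. Jun, Fos, Tgm2 and Dtl lie higher on both knockout-labelled arrays, by 4.63, 4.02, 3.90 and 2.90 on average, Ncmap lies lower by a mean difference of -3.12, and the Furin arrays overlap.

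Of the 20 gene lists with enough measured members, fixed before the data were examined, camera called 10 with its preset correlation, all higher in the knockout-labelled arrays. None of the 10 was called with an estimated correlation, where the smallest adjusted p was 0.218. With the pair as a block and the preset correlation 9 were called, and the cytokine and chemokine list was not (adjusted p = 0.106). The test fry, which asks whether a list's genes move on balance in 1 direction, called 2 lists, the interferon response and the Th1 genes (adjusted p = 0.0238 for both), and 0 with the block.

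The T cell receptor immediate early list rose (median 0.26, camera adjusted p = 4.20e-12, 9.08e-09 with the block; adjusted p = 0.218 with an estimated correlation). Of its 25 measured genes, 14 were higher and 1 was lower in both pairs. Its median was 0.52 in pair 1 and 0.27 in pair 2. Adjusted over the list alone, 2 genes passed without the block and 6 with it, namely Jun, Fos, Junb, Dusp1, Irf4 and Ppp1r15a, against 0 and 2 over all probe sets. Other members, chosen after their values were seen, differed by less. Nr4a2 was at 0.63 (0.94 and 0.32 in the pairs), Ier2 at 0.59 (0.72 and 0.46) and Cd69 at 0.44 (0.76 and 0.12), while Egr1, Egr2, Egr3, Nr4a1, Nr4a3 and Myc lay between -0.06 and 0.07. The heat shock list rose as well (median 0.39, camera adjusted p = 8.95e-08, 1.02e-07 with the block; adjusted p = 0.248 with an estimated correlation), and 10 of its 14 genes were higher in both pairs and 0 lower. Its median was 0.63 in pair 1 and 0.19 in pair 2. Hspa1b was higher by 1.82 (SE 0.39, pairs 1.35 and 2.30) and Hsph1 by 0.87 (SE 0.91, pairs 1.32 and 0.42). Adjusted over the list alone, 0 heat shock genes passed without the block and 2, Hspa1a and Hspa1b, with it. Without knockout replicate 1 the heat shock call was lost and Hsph1 was at -0.26.

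The interferon response list rose (median 0.54, camera adjusted p = 2.40e-14, 3.71e-15 with the block; adjusted p = 0.218 with an estimated correlation). It was as high in pair 1, with a median of 0.59, as in pair 2, with 0.51. Of its 30 measured genes, 26 were higher and 1 was lower in both pairs. Gbp2 and Gbp3, guanylate-binding proteins, were higher by 1.34 (SE 0.50, pairs 1.16 and 1.52) and 1.26 (SE 0.92, pairs 1.06 and 1.46), and Mx1, an antiviral GTPase, by 1.08 (SE 0.34, pairs 0.92 and 1.25). With 1 array left out Gbp3 ranged from 0.22, without wild-type replicate 2, to 2.30, and Gbp2 from 0.83 to 1.85. No member passed over all probe sets with or without the block, and 11 did with the block and a trended prior. Adjusted over the list alone, 0 passed without the block and 12 with it.

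The Th1 list rose (median 0.10, mean 0.51, camera adjusted p = 3.17e-05, 0.00258 with the block; adjusted p = 0.218 with an estimated correlation), and so did the activated and memory list (median 0.17, mean 0.39, camera adjusted p = 2.79e-05, 0.000785 with the block; adjusted p = 0.218 with an estimated correlation). In both lists the mean lay well above the median, and they share 4 measured genes. The Th1 medians in the pairs were 0.10 and 0.19, and those of the activated and memory list 0.11 and 0.26. Ccl5, a chemokine, was higher by 2.15 (SE 0.32, pairs 2.03 and 2.27), Cxcr3, a chemokine receptor of Th1 cells, by 1.48 (SE 0.38, pairs 1.32 and 1.65), Il12rb1, a chain of the interleukin 12 receptor, by 1.40 (SE 0.45, pairs 1.45 and 1.35), S100a4 by 2.10 (SE 0.79, pairs 1.36 and 2.84) and Gzma, a granule protease, by 1.78 (SE 0.46, pairs 1.35 and 2.21). With 1 array left out S100a4 ranged from 1.03, without knockout replicate 2, to 3.17. Adjusted over the list alone, 1 Th1 gene passed without the block and 4 with it, and 1 and 6 of the activated and memory genes, against 0 of either list over all probe sets, or 3 and 5 with the block and a trended prior. Of the 29 activated and memory genes, 7 were lower in both pairs, among them Cd44, the marker excluded by the sort, at -0.28 (chosen after its value was seen). With only probe sets above the 75th percentile of mean signal, the activated and memory list was no longer called (adjusted p = 0.985) and its direction turned. The cytokine list (median 0.09, 0.25 and -0.06 in the pairs, camera adjusted p = 0.0408; adjusted p = 0.598 with an estimated correlation) held 1 gene, Ccl5, that passed adjusted over the list alone, with and without the block. Its call was lost with no filter (camera adjusted p = 0.195), above the 75th percentile of mean signal (camera adjusted p = 0.431) and without knockout replicate 2. Without wild-type replicate 1 its direction turned. The cell cycle list (median 0.14, 0.04 and 0.20 in the pairs, camera adjusted p = 0.00815, 0.0180 with the block; adjusted p = 0.248 with an estimated correlation) was led by Mki67, at 0.30 in pair 1 and 1.70 in pair 2, and its call was lost when any 1 array was left out.

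Markers of cells that the sort should exclude were also higher. The myeloid list rose (median 1.09, camera adjusted p = 7.63e-10, 2.84e-12 with the block; adjusted p = 0.478 with an estimated correlation), with 14 of 16 genes higher and 0 lower in both pairs. Its median was 0.65 in pair 1 and 1.74 in pair 2. S100a8 and S100a9, calcium-binding proteins of neutrophils, were higher by 2.50 (SE 1.78, pairs 1.5 and 3.50) and 2.48 (SE 2.51, pairs 1.29 and 3.66), and Ngp, a neutrophil granule protein, by 2.53 (SE 1.07, pairs 1.84 and 3.23). S100a9 lay at 4.09 (wild type) and 5.38 (knockout) on the arrays numbered 1. Both are below the filter level of 6.24, so its pair 1 difference says little. With 1 array left out S100a8 ranged from 0.15 to 4.85, S100a9 from -0.78 to 5.74 and Ngp from 1.12 to 3.95, each lowest without knockout replicate 2. The B cell list rose (median 0.90, camera adjusted p = 0.000453, 1.86e-08 with the block; adjusted p = 0.598 with an estimated correlation), with medians of 0.23 and 1.47 in the pairs. Of its 13 measured genes, 11 were higher and 0 were lower in both pairs. Cd74 was higher by 1.54 (SE 1.57, pairs 0.95 and 2.14) and H2-Aa, of MHC class II, by 1.37 (SE 1.06, pairs 0.82 and 1.92). Other members, chosen after their values were seen, differed less in pair 1. Ms4a1 was at 0.08 and 1.71 in the pairs, Cd79a at 0.29 and 1.36, and Cd22 at -0.28 and 1.42. With 1 array left out Cd74 ranged from -0.41 to 3.50 and H2-Aa from 0.017 to 2.72, each lowest without knockout replicate 2. The 6 kept probe sets of Ighm, a B cell marker, disagreed and ran from -0.10, for the brightest, to 3.10; their mean gave 0.75. The sign of the brightest also turned without wild-type replicate 2 or knockout replicate 1. The brightest myeloid marker, Cst3, differed by 0.37 (SE 0.75, pairs 0.40 and 0.34) and turned to -0.39 without wild-type replicate 1 and -0.36 without knockout replicate 2. The next brightest, Lst1, differed by -0.02 (SE 0.42, pairs -0.21 and 0.18). The plasma cell list rose too (median 0.70, camera adjusted p = 0.00017, 0.00110 with the block; adjusted p = 0.248 with an estimated correlation), with pair medians of 0.04 and 1.23. Jchain differed by -0.56 in pair 1 and 3.50 in pair 2, and Xbp1, its brightest member, by 0.08 (SE 0.38, pairs 0.25 and -0.09). Adjusted over the list alone, 0 genes of these 3 lists passed without the block, and 11 myeloid, 2 B cell and 2 plasma cell genes with it. The 2 plasma cell genes were Derl3 and Irf4, and Irf4 is also in the T cell receptor list. Without knockout replicate 2 the myeloid and plasma cell calls were lost and the direction of the B cell list turned. The B cell call was lost without wild-type replicate 1, and the plasma cell call also without wild-type replicate 2. Leaving out 1 array mixes genotype with array number, here and in the leave-out values above, whereas within both pairs the B cell median was above 0.

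The CD8 T and NK cell list had no common direction (camera adjusted p = 0.455, medians 0.08 and -0.09 in the pairs). Ctsw, a cathepsin of cytotoxic cells, was lower at -1.60 (SE 0.44, pairs -1.49 and -1.72), while Gzma and Nkg7, at 1.78 and 1.22, were higher. Adjusted over the list alone these 3 of its 7 genes passed with and without the block. The 4 measured erythroid and platelet genes were too few to test, with medians of 0.10 and -0.76 in the pairs.

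**Figure D3:**
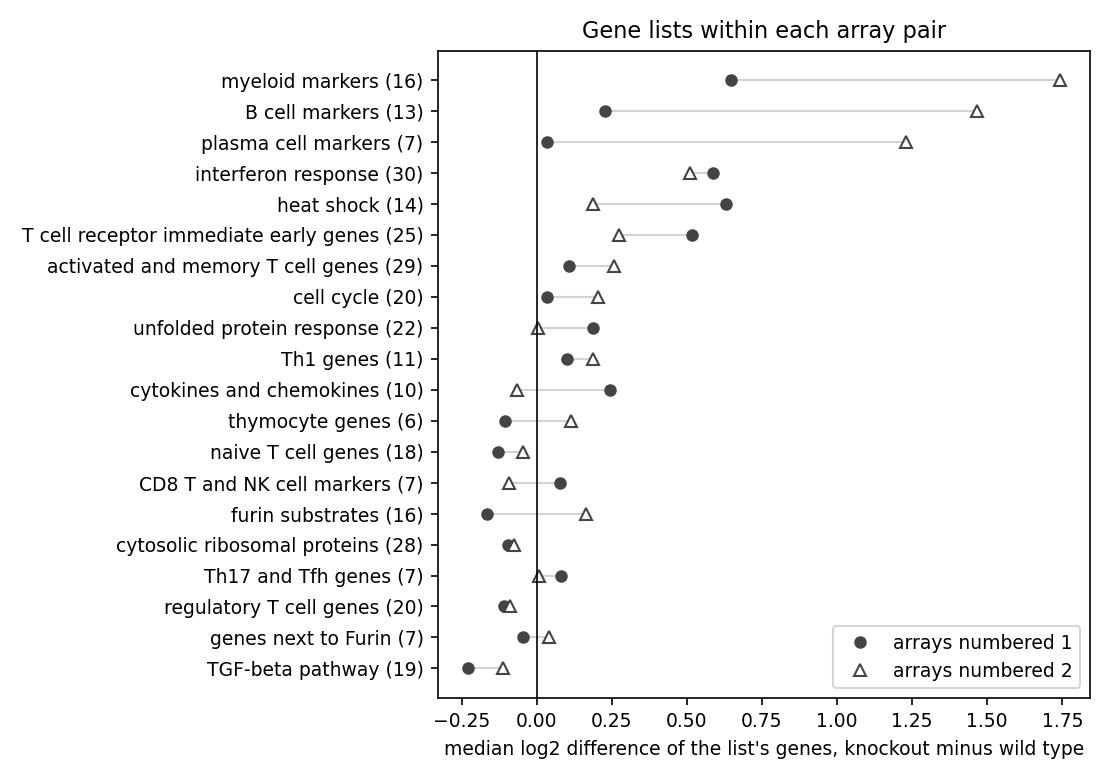
Median log2 difference, knockout minus wild type, over the measured genes of each of the 20 tested lists (number of genes in brackets), within the arrays numbered 1 (filled circles) and those numbered 2 (open triangles). The interferon list lies at 0.59 and 0.51 and the myeloid list at 0.65 and 1.74, while the lists at the foot of the plot lie close to 0.

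Lists tied to the function of furin or to the naive state did not pass. Since furin cuts precursor proteins, the mRNA levels of its substrates do not measure its activity. The TGF-beta pathway, whose ligand furin is known to process, had a median of -0.12 (-0.23 and -0.11 in the pairs, camera adjusted p = 0.412). Skil and Ltbp3 differed by -0.43 (SE 0.33, pairs -0.38 and -0.48) and 0.43 (SE 0.37, pairs 0.83 and 0.03). Furin substrates had a median of -0.07 (-0.17 and 0.16, camera adjusted p = 0.767), with Sort1 at 0.77 (SE 0.44, pairs 0.81 and 0.73) and Adam19 at -0.75 (SE 0.34, pairs -0.81 and -0.69). Naive T cell genes had a median of -0.02 (-0.13 and -0.04, camera adjusted p = 0.717), led by Dapl1 at 0.62 (SE 0.85, pairs 0.68 and 0.56) and Il6ra at -0.59 (SE 0.34, pairs -0.46 and -0.72). Regulatory T cell genes had a median of -0.10 (-0.11 and -0.09, camera adjusted p = 0.455), with Ikzf4 at -0.64 (SE 0.37, pairs -0.66 and -0.63) and Nrp1 at -0.62 (SE 0.49, pairs -0.39 and -0.86). The unfolded protein response had a median of 0.11 (0.19 and 0.01, camera adjusted p = 0.188), with Hyou1 at 0.43 (SE 0.54, pairs 0.38 and 0.48). Th17 and Tfh genes (median -0.09, 0.08 and 0.01 in the pairs, with Batf at 0.73, SE 0.55, pairs 0.88 and 0.57), thymocyte genes (median -0.01, -0.11 and 0.11 in the pairs) and the genes next to Furin each had a camera adjusted p of 0.872, and the ribosomal proteins (median -0.09, -0.10 and -0.08 in the pairs) had 0.892. In these last 4 lists, and among the CD8 T and NK cell markers, camera gave the direction as up although the median lay below 0. With the block the adjusted p of the 10 lists that were not called, the CD8 T and NK cell list included, ran from 0.170 to 0.938. No gene of these lists passed in limma, with or without the block, over all probe sets or adjusted over the list alone, apart from the 3 CD8 T and NK cell genes named above; with the block and a trended prior these 3 and Dapl1 passed over all probe sets. Of the other proprotein convertases, Pcsk7 differed by 0.15 (SE 0.34, pairs 0.23 and 0.07) and Mbtps1 by -0.09 (SE 0.35, pairs -0.06 and -0.13), and of the 4 Th2 genes, too few to test, Maf differed by 0.50 (SE 0.51, pairs 0.32 and 0.69). Among the genes with a difference given here, with 1 array left out the sign turned for Tgfb1, Dapl1, Hyou1, Pcsk7, Mbtps1 and Maf, and with the mean of a gene's probe sets for Mbtps1. Over the settings run Skil ranged from -0.54 to -0.03, the latter with the mean of its probe sets, Ltbp3 from 0.20 to 0.65, Sort1 from 0.41 to 1.13, Batf from 0.16 to 1.29, Nrp1 from -1.13 to -0.11, Ikzf4 from -0.87 to -0.42 and Il6ra from -0.79 to -0.39.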

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

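The combinations of the block with another setting, and the count within same-numbered pairs, were chosen after the data were seen. Without a block, limma called 0 probe sets under every alternative run. The replicate block is the array number in the labels, and its use as a batch rests on the hybridisation controls, since the labels state no batch. With this block limma called 6, or 9 at an adjusted p under 0.10. Combined with the block, quantile normalization gave 6, the pseudocount at the median 49 (43 higher, 6 lower), only means above the 75th percentile 140 (97 and 43) and a trended prior 260 (179 and 81), while pseudocount 1 and no filter gave 0. On data simulated from its own variance model a trended prior with the block made 12.3% false calls; the other combinations were not simulated. Probe sets 2-fold apart in all 4 comparisons numbered 46, against 175 at 1.5-fold, 178 with no filter, 19 (all higher) above the 75th percentile of means, 109 (80 and 29) within both same-numbered pairs, and 210 to 507 with 1 array left out, where fewer arrays have to agree. The Furin difference ranged from -0.055 to 0.27 with 1 array left out and turned negative without wild-type replicate 2. The 10 called lists became 0 with an estimated correlation, with or without the block, 2 with fry, 0 with the block and fry, 4 (3 higher, 1 lower) above the 75th percentile, where 13 lists were tested, 9 with the block, and 8 to 9 with 1 array left out, of which 1 was lower without wild-type replicate 1 and 3 were lower without knockout replicate 2. The direction of the activated and memory list turned above the 75th percentile (camera adjusted p = 0.985). Directions also turned for cytokines without wild-type replicate 1, for ribosomal proteins without wild-type replicate 1 or knockout replicate 2, and for B cell markers without knockout replicate 2. The ribosomal list, not called as reported, turned without passing also with the mean of probe sets, above the 75th percentile, and with median centring, the block or fry. With 1 array left out, the adjusted p ranged from 0.00423 to 0.952 for cytokines, from 2.33e-10 to 2.42e-06 for ribosomal proteins and from 3.18e-24 to 0.84 for B cell markers. Leaving out an array mixes genotype with array number, by construction; other causes were not tested. The table has no detection calls, so what background limits is not known.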

Other observations

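All tests in this part were chosen after the results were seen, and so were the gene families. All 11 measured interferon-inducible GTPases were higher in both pairs, by 0.53 to 3.84 (median 0.97, with 0.91 and 1.11 in the pairs), whereas 27.7% of all 10211 genes were higher in both pairs. All 7 measured granulocyte granule genes were likewise higher in both pairs, by 1.46 to 2.53 (median 2.37, with 1.25 and 3.23 in the pairs). Some of them were dim, so their pair 1 differences say little. S100a9 (4.09 wild type, 5.38 knockout) lay below the filter level of 6.24 on the arrays numbered 1, and Camp and Ltf had wild-type means of 5.42 and 5.73. The 2'-5' oligoadenylate synthetases, antiviral enzymes, were higher in both pairs in 6 of 7 genes (median 0.70), while the IFIT family was so in 2 of 5 genes (median 0.35). MHC class I genes went both ways, with H2-K1 at -0.23 and H2-Q5 at 1.21. Among AP-1 subunits, Jun, Fos and Junb were higher by 4.63, 4.02 and 1.80, Jund by 0.23, and Fosl2 differed by -0.55. In the HSP70 family the inducible genes Hspa1a and Hspa1b were higher by 3.44 and 1.82, and Hspa8, the constitutive member, differed by 0.03. These families were not tested as sets.

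Jun and Fos were higher on both knockout-labelled arrays, and 10 of the 14 heat shock genes were higher in both pairs. The other 23 measured genes of the T cell receptor early list had a median of 0.226 (SD between genes 0.69). Among them Egr1, Egr2, Egr3, Nr4a1, Nr4a3 and Myc, picked after their values were seen, lay between -0.06 and 0.07. The list as a whole did not rise as Jun and Fos rose. Jun and Fos are its largest changes, so this does not decide on receptor stimulation that raises some members more than others. The bound set for receptor signals, a fixed share of the mean Jun and Fos change, was 1.08. It was chosen after the values were seen and without stimulated cells for reference, so it decides nothing further. Dusp1, Ppp1r15a and Junb, at 2.27, 2.16 and 1.80, lay above the bound, so a part in the pattern stays open, and with Jun and Fos, the genes to be explained, counted in the list the spread (SD 1.26 around a median of 0.26) reached past it. Stress during isolation stays open too: the heat shock list was above 0 in both pairs, by 0.63 and 0.19 at the median, as stress could give, and no array lay at the other group's level of Jun or Fos; handling is not recorded in the labels, so it cannot be told apart from genotype here. An effect of furin loss itself stays open, untested.

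Interferon response genes were higher. More B cells and myeloid cells in the knockout sorts may raise such genes, but the interferon list differed between the pairs by 0.038 (95% bootstrap interval over genes -0.14 to 0.19), where the B cell and myeloid lists differed by 1.19 and 0.999. The list as a whole did not follow the pair difference of those markers. Interferon gene families went either way, with pair medians of 0.91 and 1.11 for the inducible GTPases and 0.59 and 0.38 for the oligoadenylate synthetases. The interval covers spread between genes only, and each pair holds 1 array of each genotype. How far such cells would shift genes already bright on wild-type arrays, such as Gbp2 at 11.4, is not known, so those cells remain possible as a source. Effector or memory cells inside the sort gate remain possible: the 29 measured activated and memory genes had a median of 0.168 (SD 0.79) and went both ways, with Ccl5, S100a4, Gzma, Cxcr3 and Nkg7 at 2.15, 2.10, 1.78, 1.48 and 1.22 and Ahnak and Cd44 at -0.67 and -0.28. The genotype stays open as well, untested.

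B cell and myeloid markers were higher, mostly in pair 2, although the sort should remove both cell types. A lower share of T cells, which would raise all other cell types alike, stays open. The 4 erythroid and platelet genes had medians of 0.104 in pair 1 and -0.76 in pair 2. The myeloid list had 0.65 and 1.74, and the B cell list 0.23 and 1.47. The CD8 T and NK cell list, also of cells that the sort should exclude, had 0.08 and -0.09. Its genes went both ways, with Gzma and Nkg7 at 1.78 and 1.22 and Ctsw at -1.60, so it does not decide the question. In pair 2 all 4 erythroid and platelet genes were lower, which goes against a shared rise, but a pair holds 1 array of each genotype. On the arrays numbered 1, Alas2 (4.26 wild type, 4.34 knockout) and Slc4a1 (5.15 and 5.28) lay below the filter level of 6.24, so their pair 1 values say little. A different carry-over of myeloid and B cells between sorts and a difference between the mice could each remain, untested.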
